A study of Mus musculus with 6 samples.

How the data were processed

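RNA of single liver cells was measured in 6 mouse libraries, 2 from each of 3 groups: control livers, livers in a pre-metastatic stage and livers with macro-metastases in an orthotopic model of colorectal cancer. The labels name CT26-GFP, a mouse colon carcinoma line carrying green fluorescent protein, for all 6 libraries. No GFP feature was used here. Per the labels' protocols, whole livers were minced, digested with collagenase II, sieved, freed of erythrocytes by lysis and depleted of dead cells with magnetic beads before capture on the BD Rhapsody system, which tags each transcript with a cell barcode and a unique molecular identifier (UMI). Enzyme digestion and dead-cell removal can lose fragile cells such as hepatocytes, so shares describe captured cells. Any effect of this handling on transcripts was not tested. The labels number the replicates within each group. Nothing states that the replicates are separate animals, so p-values measure only the spread between these samples, which may be technical.

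The deposited values are UMI counts per gene and cell barcode, not normalised. Per the submitters' processing notes, reads were handled with CASAVA 1.8 and UMI-tools on the mouse genome build mm10. The aligner and the gene annotation are not given in the sources used here. The matrices hold 31253 features and 71908 barcodes, each with at least 500 UMIs. Total UMIs per library were 44976402 and 41914149 in control, 48764379 and 51750676 in pre-metastatic, and 88986627 and 90819751 in macro-metastatic libraries. Coordinates, GC content and transcript lengths came from the GENCODE annotation of the matching build.

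Barcodes with at least 300 genes and under 25% mitochondrial UMIs were kept. Doublets were predicted in each library by comparison with simulated pairs of cells, at a common score threshold of 0.268 and an expected rate of 6%, and left out after clustering. This left 65275 cells. Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 51 clusters (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, Python 3.11.15). No batch integration was applied. Each cluster took the name of the cell type whose markers it held at the highest relative level, if at least 3 of those markers were detected in at least 10% of its cells and its 10 leading genes did not hold more markers of another class. A class name stands for cells like that type. Clusters with over 30% predicted doublets were set apart as mixed.

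Cells are not replicates. Cells per class and library were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with kept cells as library size and Benjamini-Hochberg adjustment over 17 classes. For 6 classes, UMI counts were summed per library and tested with edgeR's quasi-likelihood test after filterByExpr and TMM scaling, with Benjamini-Hochberg adjustment over the genes tested. All 6 libraries entered each fit, which left 3 residual degrees of freedom. A fit that leaves out a library keeps a single library in that group, and its spread then comes from the other groups only. A call is an adjusted p under 0.05. An exact permutation test of 2 against 2 libraries cannot go below p = 0.3333, so no such test was run. Fixed gene lists were tested with limma's camera (limma 3.58.1, two-sided) at a preset inter-gene correlation of 0.01. Lists with fewer than 3 measured genes in a class were not tested. With the correlation estimated from the data, no list stayed called in any class or comparison. The p of that test is given with each called list.

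Named genes followed a rule: in each class and comparison the 4 rising and 4 falling genes with the largest log2 fold change among called genes with a mean log2 CPM of at least 5, both libraries of the groups separated, and CPM in the class of at least 10% of the highest in any other class. For this last condition CPM were pooled over all 6 libraries, so it does not screen a single group. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and unnamed predicted genes were left out. List members were taken by smallest adjusted p, up to 4 per list, and 1 member taken so is not reported here. Levels are CPM of the summed UMIs on TMM-scaled library sizes, given as mean ± SD with n = 2 libraries, and log2 fold changes carry their SE. Ratios, lower bounds, percentages of the level in another class and CPM of single libraries use unscaled sums, so they can differ from these levels. Where the controls held no UMI of a gene, the fold is a lower bound against a floor of 3 counts over the group. Where they held 1 to 3 UMIs, the ratio of macro-metastatic to control livers is given with an exact 95% counting interval. Shares of single libraries carry Wilson 95% intervals. Intervals and floors cover counting error only.

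Groups, tests, markers, gene lists and the rule for named genes were fixed before the data were examined, as were the alternatives: other scalings, DESeq2 1.42.0, no filter on low counts, stricter cell filters (500 genes, 10% mitochondrial UMIs), genes screened for RNA from other cells, doublets kept, Leiden resolution 2, immune cells only, the replicate number as a block, and leaving out each library. Added after the data were seen were a fit of B cells, the change of each class relative to the B cells of the same libraries, a correction for GC content and transcript length, thinning to the shallowest library, and Kupffer cells less a cluster rich in endothelial transcripts. The steps were tested on simulated counts with 200 changed genes. In the simulated macro-metastatic against control comparison, 4-fold changes were recovered for 55.2% of the changed genes in neutrophils (7894 genes tested), 58.1% in monocytes and macrophages (10227), 87.9% in Kupffer cells (13096), 89.8% in endothelial cells (12614), 89.9% in T cells and 85.7% in NK cells. For 2-fold changes the recovery was 7.53%, 4.95%, 54.3%, 37.4%, 53.9% and 47.1%. Among calls, 4.76% to 12.5% were false. For cell classes, 51 of 80 simulated 8-fold changes were recovered, with 3 false calls among 260.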

Results

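The cellular make-up of the mouse liver and the transcripts of its cells were compared between control livers, pre-metastatic livers and livers with macro-metastases of colorectal cancer, to follow the liver microenvironment as metastasis progresses. After filtering, 9232 and 10112 cells remained in the control libraries, 10087 and 10423 in the pre-metastatic libraries, and 11726 and 13695 in the macro-metastatic libraries. The median UMI count per barcode was 2412 and 2467.5 in control, 2454 and 2843 in pre-metastatic, and 4234 and 3302 in macro-metastatic libraries, so the macro-metastatic libraries were the deepest. Endothelial cells (15499 cells), T cells (9801), neutrophils (9688) and Kupffer cells (7680), the resident macrophages of the liver, were the most numerous classes. Clusters left unnamed held 4.78%, 6.91% and 6.90% of cells in the 3 groups, and mixed clusters 0.430%, 1.08% and 0.976%. Xist, the X-inactivation transcript of female cells, had at least 14638 UMIs in each library and the Y-linked genes Uty and Ddx3y at most 30 and 9.

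Among captured cells, the shares of myeloid cells were larger and those of lymphocytes and hepatocytes smaller in macro-metastatic than in control livers. Neutrophils made up 1.75% ± 0.699 of cells in control and 27.9% ± 2.50 in macro-metastatic livers (SD, n = 2 each). Monocytes and macrophages rose from 0.753% ± 0.207 to 12.1% ± 8.68 and Kupffer cells from 6.57% ± 0.737 to 15.2% ± 0.142. T cells fell from 25.3% ± 10.1 to 6.01% ± 3.04, NK cells from 2.84% ± 0.731 to 0.735% ± 0.437, B cells from 7.57% ± 0.961 to 3% ± 1.06, and hepatocytes from 6.56% ± 1.25 to 0.433% ± 0.420. These 7 of 17 classes passed edgeR's quasi-likelihood test, with log2 fold changes of 4.03 (SE 0.449, adjusted p = 0.00231) for neutrophils, 4.04 (SE 0.818) for monocytes and macrophages, 1.25 (SE 0.279) for Kupffer cells and −3.87 (SE 0.832) for hepatocytes, the last 3 at adjusted p = 0.0198. T cells changed by −2.03 (SE 0.506, adjusted p = 0.0260), B cells by −1.29 (SE 0.387) and NK cells by −1.90 (SE 0.592), both at adjusted p = 0.0474. Endothelial cells, at 37.7% ± 8.65 in control and 16.4% ± 2.71 in macro-metastatic livers, did not pass (log2 fold change −1.16, adjusted p = 0.0766). Shares add up to the same total in every library, so a rise of neutrophils lowers all other shares. With immune cells alone as the total 6 classes passed, Kupffer cells not among them (adjusted p = 0.216). With TMM factors over the classes Kupffer, NK (0.0931) and B cells (0.162) were not called. With the replicate number as a block 11 classes passed, and endothelial cells had adjusted p = 0.0509. Without control replicate 1, or without control replicate 2, only neutrophils and Kupffer cells stayed called. The other 5 classes had adjusted p = 0.151 in the former case and 0.112 to 0.247 in the latter.

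Cells of the tumour class, whose leading genes included the intestinal epithelial keratin Krt20, numbered 0 and 1 in the control libraries, 0 and 0 in the pre-metastatic libraries, and 4 and 428 in the macro-metastatic libraries. In macro-metastatic replicate 2 they made up 3.13% of cells (Wilson 95% interval 2.85 to 3.43), against 0.0341% in macro-metastatic replicate 1. The Wilson interval of a count of 0 reaches 0.0381% and 0.0368% in the pre-metastatic libraries. The class did not pass edgeR's quasi-likelihood test between macro-metastatic and control livers (adjusted p = 0.0654), but passed with the replicate number as a block (0.00701).

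In pre-metastatic livers, neutrophils made up 11.2% ± 3.15 of cells and conventional dendritic cells, which present antigen to T cells, 5.76% ± 0.556, against 1.75% ± 0.699 and 1.55% ± 0.141 in control livers. These 2 classes passed edgeR's quasi-likelihood test, with log2 fold changes of 2.71 (SE 0.424, adjusted p = 0.0139) and 1.93 (SE 0.388, adjusted p = 0.0239). Kupffer cells (12.4% ± 0.0190, log2 fold change 0.96) and monocytes and macrophages (5.42% ± 3.76, log2 fold change 2.88) had adjusted p = 0.0609. T cells were at 16.6% ± 2.87, NK cells at 2.25% ± 0.217, B cells at 6.17% ± 0.0189, endothelial cells at 19.2% ± 10 and hepatocytes at 7.76% ± 1.59. Without control replicate 1 neither class was called (adjusted p = 0.0527 for neutrophils and 0.116 for dendritic cells). Dendritic cells lost the call without control replicate 2 (0.0908), pre-metastatic replicate 1 (0.254) or pre-metastatic replicate 2 (0.160), with TMM factors (0.269) and with immune cells alone as the total (0.148). Between macro-metastatic and pre-metastatic livers edgeR's quasi-likelihood test called 0 classes, while 7 had an unadjusted p under 0.05 and 5 each were called by DESeq2 and with the replicate number as a block. The adjusted p nearest to a call was 0.0508, for hepatocytes (log2 fold change −4.15). Without macro-metastatic replicate 1 it called 3 classes, hepatocytes, tumour cells and stellate cells, and without macro-metastatic replicate 2 it called 8.

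**Figure D1:**
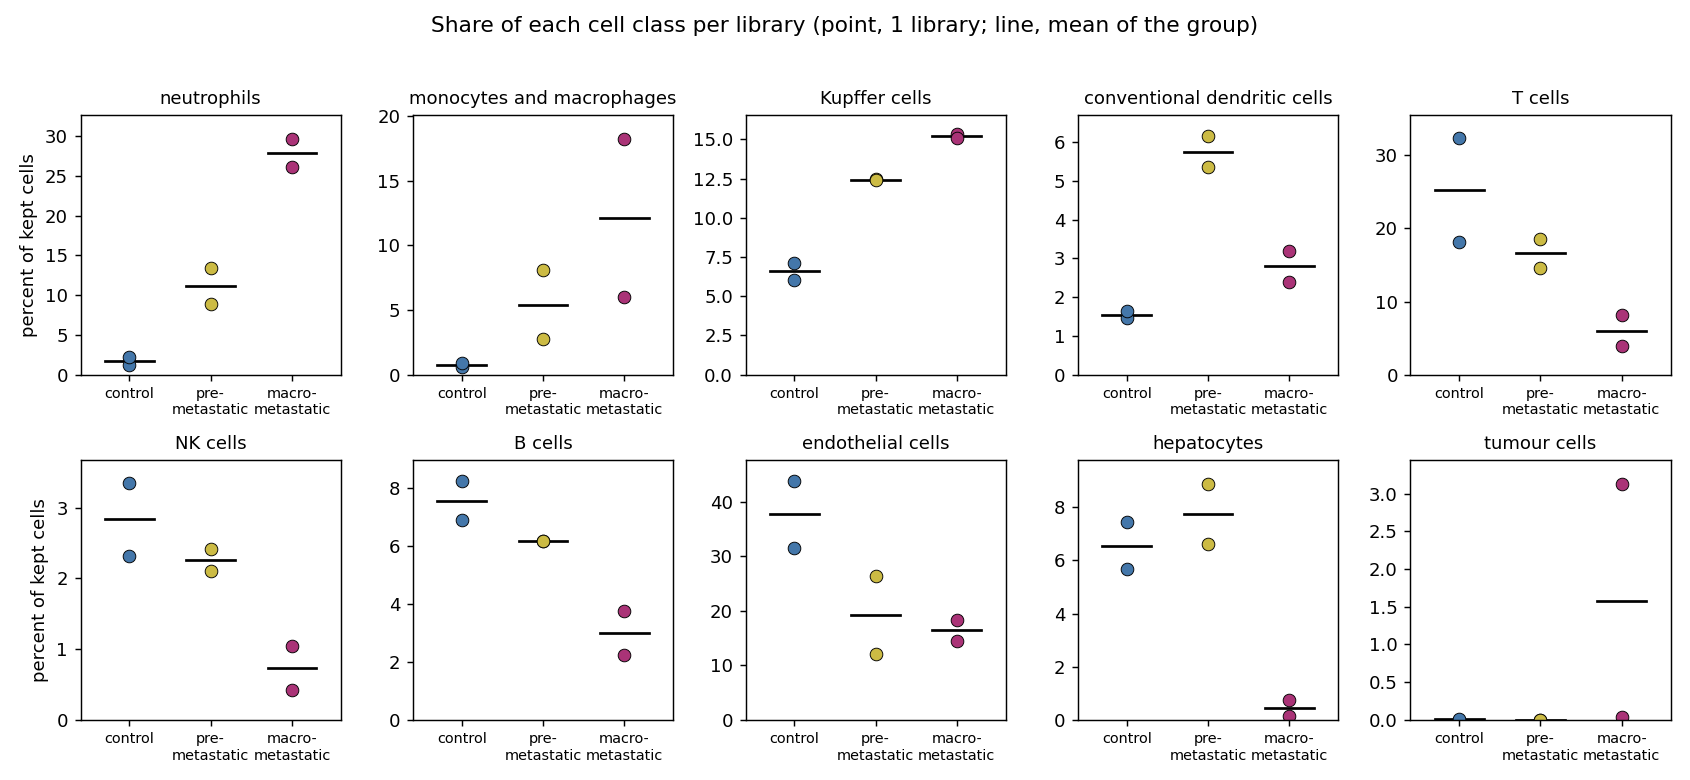
Share of kept cells (percent, vertical axis) in 10 classes for the 3 groups, with points for libraries and lines for group means. Neutrophils stand at 1.75% in control, 11.2% in pre-metastatic and 27.9% in macro-metastatic livers, and T cells at 25.3%, 16.6% and 6.01%.

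A set of genes was higher in every class of the macro-metastatic libraries. Of 5303 genes tested in all 7 classes with B cells included, 139 had a log2 fold change over 1 against control in every class and 12 had a change below −1 in every class. The 139 genes had a median change of 2.22, between 1.94 and 2.31 in the single classes. Among them were Gapdh and Pkm, enzymes of glycolysis (2.87 and 2.10 in the median class), Eef2, a translation elongation factor (3.02), Ppp1ca, a phosphatase subunit (3.97), and the ribosomal protein genes Rpl8 (3.46) and Rpl28 (3.83). Cxcl1, Ccl2, Cd14, Hilpda, Il4ra, Lgals3, Slfn2, Gpi1 and Mt2, named below in single classes, belong to the set as well. Of the 139 genes, 26 share over 10% of the 31-mers of their last 500 bases with another gene, Gapdh among them (41.7%), so their levels are uncertain. The median GC content of these last 500 bases was 51.4%, against 41.4% in all genes compared. In the pre-metastatic libraries the 139 genes had a median change of 0.118. Across genes, which are not independent replicates, the log2 fold changes of 21 pairs of classes correlated with Spearman's rho of 0.395 to 0.697. The change relative to the B cells of the same libraries is therefore given for each class beside its count of changed genes.

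**Figure D2:**
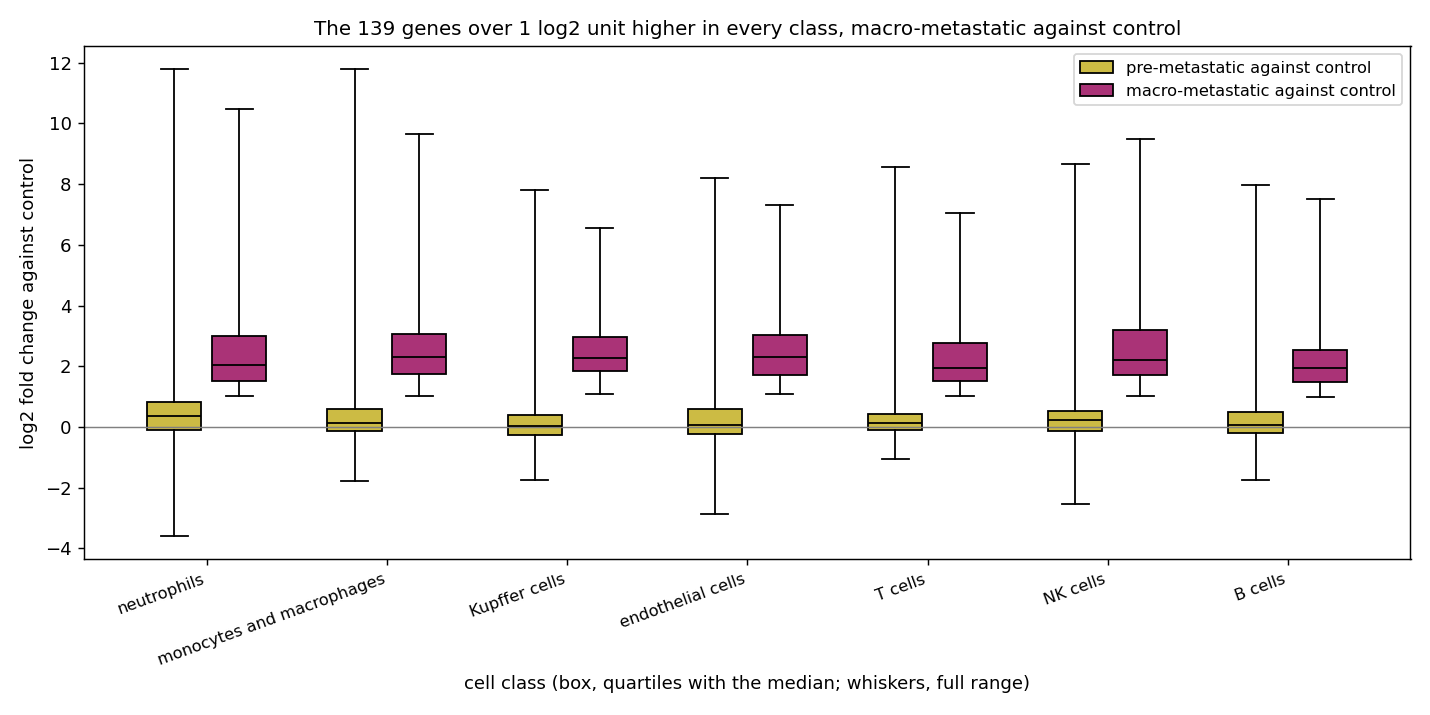
Log2 fold change against control (vertical axis) of the 139 genes over 1 higher in every class of the macro-metastatic libraries, by cell class (horizontal axis) for pre-metastatic and macro-metastatic livers, with boxes for quartiles, lines for medians and whiskers for the full range. Class medians lie between 1.94 and 2.31 for the macro-metastatic livers, and their median is 0.118 for the pre-metastatic livers.

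Lists of transcripts that mark other cell types moved in most classes as well. A class may make some of these transcripts itself, which was examined only for neutrophil transcripts in lymphocytes and endothelial cells. Neutrophil transcripts, such as S100a8 and S100a9 for calprotectin, rose in macro-metastatic against control livers for 12 of 12 members in Kupffer cells, 11 of 12 in endothelial cells, 9 of 10 in T cells, 4 of 5 in NK cells and 4 of 10 in monocytes and macrophages (12, 12, 9, 4 and 7 adjusted over the list alone). Camera gave adjusted p = 1.51e-05, 6.59e-09, 1.34e-06, 4.16e-07 and 0.000106. Their adjusted p with an estimated correlation was 0.484, 0.208, 0.490, 0.209 and 0.417. In B cells S100a8 and S100a9 stood at 0.0139% and 0.0229% of the neutrophil level in the control libraries, 0.224% and 0.141% in the pre-metastatic libraries, and 1.28% and 0.742% in the macro-metastatic libraries. Hepatocyte transcripts fell for 13 of 19 members in T cells, 13 of 19 in B cells, 9 of 20 in endothelial cells, 8 of 19 in neutrophils, 8 of 19 in monocytes and macrophages and 7 of 12 in NK cells (14, 13, 10, 12, 10 and 9 adjusted over the list alone). Their camera adjusted p was 2.42e-06, 1.27e-07, 0.00213, 0.000182, 1.44e-06 and 2.39e-07. With an estimated correlation these had adjusted p = 0.490, 0.381, 0.581, 0.675, 0.140 and 0.242. Acute-phase transcripts, which hepatocytes make in inflammation, rose for 10 of 11 members in Kupffer cells, 9 of 12 in endothelial cells, 5 of 11 in T cells, 1 of 11 in neutrophils and 1 of 10 in monocytes and macrophages (10, 11, 5, 1 and 1 adjusted over the list alone), with camera adjusted p = 7.25e-06, 1.79e-07, 0.0229, 0.0318 and 0.00920 and adjusted p = 0.303, 0.208, 0.625, 0.610 and 0.496 with an estimated correlation. T cell transcripts fell for 6 of 10 members in Kupffer cells (7 adjusted over the list alone, camera adjusted p = 0.00932, adjusted p = 0.680 with an estimated correlation). Without control replicate 2 the acute-phase call was lost in T cells (0.165), neutrophils (0.561) and monocytes and macrophages (0.0987). It was also lost in T cells without macro-metastatic replicate 2 (0.175) and in neutrophils without pre-metastatic replicate 2 (0.0515), and the hepatocyte call in endothelial cells without macro-metastatic replicate 1 (0.0628).

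Neutrophils of macro-metastatic livers held more transcript of Prok2, a secreted chemoattractant (chromosome 6, 99711299 to 99726392), at 475 ± 26.6 CPM against 6.81 ± 0.228 in control (ratio 64.5, counting interval 22.1 to 313 from 3 control UMIs). Cd177, a neutrophil surface antigen, was at 387 ± 292 against 16.9 ± 4.25 CPM (log2 fold change 4.59, SE 0.80, adjusted p = 0.00899), with 40.6% of its 31-mers shared with another gene. Stfa3, a cysteine protease inhibitor, rose 27.1-fold (counting interval 4.85 to 1071) and Itprip 26.6-fold (4.76 to 1050), each from 1 control UMI. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis (chromosome 1, 150100031 to 150108227), fell by 3.15 on the log2 scale (SE 0.20, adjusted p = 0.000142), from 3214 ± 13.6 to 363 ± 52.1 CPM. Egr1, an immediate-early transcription factor, fell by 2.76 (SE 0.29), Pmaip1, which promotes apoptosis, by 2.77 (SE 0.22) and Tspan2 by 3.21 (SE 0.33). Among hypoxia and glycolysis genes 7 of 20 rose and 1 fell (11 and 2 adjusted over the list alone), led by Gapdh (3.90), Gpi1 (2.21) and Pkm (2.10). Among myeloid suppressor genes 9 of 18 rose and 1, Ptgs2, fell (12 and 1 adjusted over the list alone), with Wfdc17 at 4.21 and Cd14 at 1.59 (4.70 in B cells). Immediate-early and heat-shock genes fell for 8 of 20 members, Btg2 (−2.26) and Egr1 among them, and rose for 3 (10 and 3 adjusted over the list alone). Whether tissue handling and digestion shifted this list was not tested, in neutrophils or in any other class. Camera called hypoxia and glycolysis (adjusted p = 0.00160), myeloid suppressor genes (0.0118), immediate-early and heat-shock genes (0.0101) and oxidative phosphorylation (0.0130, with 5 of 29 genes up, also 5 adjusted over the list alone). The lists had, with an estimated correlation, adjusted p = 0.610, 0.372, 0.372 and 0.610. Neutrophil granule genes (1 of 16 up), NF-kB inflammatory cytokines (7 up and 2 down of 19), interferon-stimulated genes (1 of 26 up), MHC class I genes (1 of 14 up) and cell cycle genes (0 of 22) were not called, at adjusted p = 0.135, 0.150, 0.830, 0.194 and 0.0924.

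In all, 817 of 7936 genes changed in neutrophils (436 up, 381 down) by edgeR's quasi-likelihood test, 282 up and 400 down after the GC and length correction, at summed depths of 145032 to 9026583 UMIs per library. Set against B cells, 153 of 5973 genes differed, 104 of them among the 522 changed genes that could be compared, with Egr1 at −4.84 (adjusted p = 1.44e-05) and Pmaip1 at −2.10 (0.000516). For 8 of 15 immediate-early and heat-shock genes the change lay below that in B cells, which a rise in B cells can also give. Camera called this list (adjusted p = 3.38e-05, 0.404 with an estimated correlation) and oxidative phosphorylation (0.0404, 0.743 with an estimated correlation). Hypoxia and glycolysis (0.288) and myeloid suppressor genes (0.581) were not called in that comparison. Most neutrophils lay in cluster 8 in control and pre-metastatic livers and in cluster 0 in macro-metastatic livers. The count was 153 without control replicate 1 and 119 without control replicate 2. Prok2, Cd177, Stfa3 and Itprip then had adjusted p of 0.0501 to 0.0681 and of 0.0809 to 0.192. Without control replicate 2 hypoxia and glycolysis and the immediate-early genes had adjusted p = 0.0835, oxidative phosphorylation 0.561 and myeloid suppressor genes 0.162 (0.0514 without control replicate 1).

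Monocytes and macrophages of macro-metastatic livers held more transcript of Il10, an anti-inflammatory cytokine (chromosome 1, 131019845 to 131024974), at 219 ± 7.68 CPM (ratio to control 125, counting interval 22.4 to 4939 from 1 control UMI). Cxcl3, a neutrophil-attracting chemokine, rose 91.1-fold (counting interval 25.2 to 752) and Slc7a11, the cystine and glutamate antiporter, 31.4-fold (8.68 to 259), each from 2 control UMIs. Hilpda, a lipid droplet protein induced by hypoxia, rose from 51.3 ± 9.62 to 1275 ± 230 CPM (log2 fold change 4.66, SE 0.52, adjusted p = 0.0114), with B cells at 2.20. Zfp217 fell by 2.27 (SE 0.24), Calhm2 by 2.14 (SE 0.23), Grk3 by 2.13 (SE 0.32) and Adgre4 by 2.09 (SE 0.43). Hypoxia and glycolysis genes rose for 10 of 24 members (14 adjusted over the list alone; Gapdh 3.11, Pkm 2.48). Myeloid suppressor genes rose for 7 of 18 (14 adjusted over the list alone), among them Clec4e (2.82) and Il4ra (3.79, with B cells at 2.27). Lipid-associated macrophage genes rose for 4 of 18 members (11 adjusted over the list alone), with the galectins Lgals1 (1.94) and Lgals3 (1.49, with B cells at 1.26) and the actin-capping gene Capg (1.89). NF-kB inflammatory cytokines rose for 4 of 20 (8 adjusted over the list alone), with Ccl2, which attracts monocytes, at 2.72 (3.64 in B cells, 4.25 in T cells and 6.84 in NK cells) and the inflammasome gene Nlrp3 at 1.87. Camera called these lists at adjusted p = 1.66e-06, 1.44e-06, 0.000105 and 0.00493. It called oxidative phosphorylation (6 of 30 up, 12 adjusted over the list alone) and cell cycle genes (1 of 19 up, also 1 adjusted over the list alone) at 0.00115 and 0.0183. With an estimated correlation these 6 lists had adjusted p = 0.399, 0.140, 0.393, 0.632, 0.535 and 0.463. Interferon-stimulated genes (1 of 26 up), MHC class II genes (1 of 9 up), MHC class I genes (1 of 14 up) and immediate-early genes (3 up and 2 down of 20) were not called (adjusted p = 0.855, 0.925, 0.883 and 0.319).

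In edgeR's test 432 of 10291 genes changed in monocytes and macrophages (339 up, 93 down), and 215 after the GC and length correction (126 up, 89 down). Relative to B cells 48 of 7278 differed, 19 of them among the 278 changed genes compared. Lists were tested relative to B cells only on the members that could be compared, not on all members measured in the class. Hypoxia and glycolysis genes (camera adjusted p = 0.00406), oxidative phosphorylation (0.00202) and lipid-associated macrophage genes (0.0476) stayed called relative to B cells, each with adjusted p = 0.459 with an estimated correlation. Myeloid suppressor genes (0.166) and cell cycle genes (0.924) did not. Only 56 and 91 such cells were held by the control libraries. Cluster 12 held most of them in control and pre-metastatic livers, and clusters 14 and 16 in macro-metastatic livers. The count was 0 without control replicate 1 and 0 without control replicate 2, where the 8 genes named first had adjusted p of 0.0706 to 0.161 and of 0.0569 to 0.136. It was 21 without macro-metastatic replicate 1 and 81 without macro-metastatic replicate 2, and 660 and 804 without pre-metastatic replicates 1 and 2. Zfp217, Lgals1, Lgals3, Capg, Nlrp3, Calhm2, Grk3 and Adgre4 lost their calls without macro-metastatic replicate 1 (0.0564 to 0.165). All of these but Zfp217 and Lgals1 also lost theirs without macro-metastatic replicate 2 (0.0538 to 0.178). So did Adgre4 with the replicate number as a block (0.0513) and after the GC and length correction (0.0574), and Calhm2 after thinning (0.0639). Without control replicate 2 NF-kB inflammatory cytokines (0.0826), oxidative phosphorylation (0.262) and cell cycle genes (0.5) lost their calls. Cell cycle genes also lost theirs without pre-metastatic replicate 1 (0.122), macro-metastatic replicate 1 (0.311) and macro-metastatic replicate 2 (0.0984).

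Kupffer cells of macro-metastatic livers held more transcript of Gda, guanine deaminase (chromosome 19, 21391307 to 21473445), at 349 ± 114 CPM against 13.4 ± 0.728 in control (log2 fold change 4.70, SE 0.32, adjusted p = 2.24e-05). Slfn2 was at 621 ± 52.8 against 28.9 ± 0.655 CPM (log2 fold change 4.43, with B cells at 1.49). Il1rn, the interleukin-1 receptor antagonist, rose by 4.26 on the log2 scale (SE 0.24) and Il10 by 4.17 (SE 0.19), from 12.6 ± 2.67 to 228 ± 31.5 CPM. NF-kB inflammatory cytokines rose for 18 of 20 members and fell for 1 (the same counts adjusted over the list alone), led by Ptgs2 (3.46, SE 0.22), the neutrophil-attracting chemokine Cxcl1 (3.01, with B cells at 4.12 and T cells at 4.43) and Nlrp3 (2.73). Among Kupffer cell identity genes 12 of 18 rose and 1 fell (12 and 1 adjusted over the list alone): Pltp, a phospholipid transfer protein (3.47, SE 0.16), the scavenger receptor Marco (2.86, SE 0.18) and the lectin Clec4f (1.62) were higher and the iron exporter Slc40a1 lower (−1.44, SE 0.14). Hypoxia and glycolysis genes rose for 14 of 24 members and fell for 3 (15 and 3 adjusted over the list alone; Gapdh 2.87, Pkm 2.18). Lipid-associated macrophage genes rose for 10 of 17 and fell for 2 (10 and 2 adjusted over the list alone). Clec14a (−5.90) and Cyp4b1 (−5.49), leading genes of endothelial cluster 1, fell with Tmem204 (−5.45) and Ces2g (−5.42). In Kupffer cells 11 endothelial markers stood at a median of 26.4% of their endothelial level in control, 18.6% in pre-metastatic and 2.37% in macro-metastatic livers, with Cdh5 and Pecam1 at 43.0% and 25.8% in the last. Camera called the 4 lists at adjusted p = 8.31e-08, 0.00122, 0.000693 and 0.0375. With an estimated correlation the adjusted p was 0.507, 0.484, 0.303 and 0.507. Interferon-stimulated genes (8 of 27 up), MHC class II genes (3 of 9 up), MHC class I genes (3 up and 1 down of 14), oxidative phosphorylation (11 up and 1 down of 30), cell cycle genes (3 up and 1 down of 24) and immediate-early genes (7 up and 3 down of 20) were not called (adjusted p = 0.289, 0.148, 0.228, 0.0610, 0.399 and 0.289).

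In edgeR's test 5172 of 13156 genes changed in Kupffer cells (2734 up, 2438 down). After the GC and length correction 2228 were up and 2639 down. When cluster 10, rich in endothelial transcripts, was left out, 3030 changed (1864 up, 1166 down), with 2684 genes called both ways. Mki67 and Top2a, of the cell cycle list, then fell by 0.52 and 1.04 (adjusted p = 0.0450 and 0.0128), although they were 0.94 and 0.47 higher with the cluster in. Cluster 10 held 432 and 376 of the 655 and 612 control Kupffer cells and 12 and 13 of the macro-metastatic ones. Without it cluster 31, led by cell cycle genes among others, made up 50 of 223 and 45 of 236 control cells against 86 of 1783 and 136 of 2056 macro-metastatic cells. Gene lists were not tested with cluster 10 left out. Changes of lists, Kupffer cell identity genes among them, can therefore reflect the mix of clusters. Set against B cells, 931 of 7448 genes differed, 589 of them among the 2747 changed genes compared, and neither hypoxia and glycolysis (camera adjusted p = 0.0703) nor lipid-associated macrophage genes (0.138) were called. Clusters 9 and 10 held most Kupffer cells in control and pre-metastatic livers and cluster 7 in macro-metastatic livers. The count was 2717 without control replicate 1 and 3373 without control replicate 2.

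Endothelial cells of macro-metastatic livers held transcripts of leukocyte adhesion at far higher levels. Sele, E-selectin, was at 170 ± 30.6 CPM against 1.13 ± 0.0309 in control (log2 fold change 7.21, SE 0.75, adjusted p = 0.00138). Lrg1, a secreted glycoprotein of vessel growth (chromosome 17, 56119678 to 56122001), was at 212 ± 4.06 against 2.19 ± 0.354 CPM (6.57, SE 0.19, adjusted p = 1.97e-05). Adamts4, a protease of the extracellular matrix, rose by 6.71 (SE 0.29) and the metallothionein gene Mt2 by 6.83 (SE 0.66), where B cells rose by 6.02. Bmp6, which sinusoidal endothelium makes to induce hepcidin, fell by 2.04 (SE 0.14), from 263 ± 5.83 to 64.1 ± 2.29 CPM, Hlf by 3.48 (SE 0.35), Ccn2 by 2.26 (SE 0.32) and Ackr4 by 2.08 (SE 0.33). Endothelial adhesion and chemokine genes rose for 10 of 15 members (11 adjusted over the list alone), among them Selp (5.01, SE 0.39), Icam1 (3.97, SE 0.29) and Vcam1 (2.62). NF-kB inflammatory cytokines rose for 15 of 19 (15 adjusted over the list alone), led by Cxcl1 (4.39, SE 0.28, with B cells at 4.12) and Nlrp3 (3.28). Immediate-early and heat-shock genes rose for 13 of 20 members (16 adjusted over the list alone; Nr4a1 3.32, Klf6 1.52), hypoxia and glycolysis genes for 15 of 24 (18 adjusted over the list alone). Angiogenesis genes rose for 7 of 18 (8 adjusted over the list alone), with the basement membrane collagens Col4a2 (1.31) and Col4a1 (1.27) and the surface protein Cd93 (0.95). Camera called these 5 lists at adjusted p = 6.18e-06, 1.90e-08, 1.91e-06, 6.97e-07 and 0.00647, cell cycle genes (10 up and 1 down of 21, 10 and 1 adjusted over the list alone) at 0.00103 and interferon-stimulated genes (8 of 27 up, 9 adjusted over the list alone) at 0.0445. With an estimated correlation the 7 had adjusted p = 0.208, 0.4, 0.471, 0.208, 0.208, 0.424 and 0.786. Sinusoidal identity genes were not called (adjusted p = 0.953): of 18, 3 rose, Plxnc1 (0.79), Lyve1 (0.89) and Stab1 (0.74), and 2 fell, Wnt2 (−0.59) and Maf (−0.62). MHC class II genes (1 of 9 up), MHC class I genes (2 of 14 up) and oxidative phosphorylation (7 up and 2 down of 30) were not called either (adjusted p = 0.256, 0.240 and 0.0630).

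In edgeR's test 2753 of 12663 genes changed in endothelial cells (1853 up, 900 down), and after the GC and length correction 1321 were up and 1393 down. Relative to B cells 316 of 7435 differed, 190 of them among the 1495 changed genes compared. For 13 of 15 immediate-early and heat-shock genes the change lay above that in B cells (camera adjusted p = 4.01e-09, 0.465 with an estimated correlation). Hypoxia and glycolysis genes were called in that comparison (0.00255, 0.294 with an estimated correlation). Cell cycle (0.704) and interferon-stimulated genes (0.682) were not. Clusters 1 and 2 held most endothelial cells in control and pre-metastatic livers and cluster 4 in macro-metastatic livers. The count was 580 without control replicate 1 and 722 without control replicate 2. Without control replicate 1 Ackr4 (0.0531), Cd93 (0.0700), Plxnc1 (0.120), Lyve1 (0.133), Stab1 (0.0868) and Wnt2 (0.130) lost their calls, the last 5 also without control replicate 2 (0.0621 to 0.164) and Lyve1 (0.0503) and Wnt2 (0.0549) without macro-metastatic replicate 2. Wnt2 lost its call without pre-metastatic replicate 1 (0.0581) or pre-metastatic replicate 2 (0.0515) as well. Interferon-stimulated genes lost their call without control replicate 2 (0.281), without macro-metastatic replicate 1 (0.882) and with the replicate number as a block (0.0551).

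T cells of macro-metastatic livers held more transcript of Pdcd1, the inhibitory receptor PD-1 (chromosome 1, 94038305 to 94052553), at 258 ± 18.1 CPM against 8.87 ± 2.26 in control (log2 fold change 4.89, SE 0.23, adjusted p = 6.21e-06). Tnfrsf9, the costimulatory receptor 4-1BB, was at 260 ± 90.9 against 15.5 ± 0.862 CPM (4.05, SE 0.28). The killer lectin-like receptor gene Klrh1 rose 281-fold (counting interval 95.7 to 1369 from 3 control UMIs). Granzyme F, Gzmf, was at least 337-fold higher (555-fold from macro-metastatic replicate 1 alone and 250-fold from macro-metastatic replicate 2 alone), with no control UMI and 21.1% of its 31-mers shared with another gene. Egr1 fell by 2.44 on the log2 scale (SE 0.20), Art2b by 3.07 (SE 0.29), Cpeb1 by 2.6 (SE 0.29) and Lpar6 by 2.37 (SE 0.20). Inhibitory receptor and exhaustion genes rose for 11 of 13 members and fell for 1 (11 and 1 adjusted over the list alone), among them Rgs16 (4.71, SE 0.43) and the inhibitory receptor gene Ctla4 (1.42, SE 0.15). Cytotoxic effector genes rose for 9 of 17 (14 adjusted over the list alone; Cst7 1.57), regulatory T genes for 6 of 10 (6 adjusted over the list alone), with the receptors Tnfrsf18 (3.01) and Tnfrsf4 (2.49). Hypoxia and glycolysis genes rose for 11 of 23 and fell for 2 (11 and 2 adjusted over the list alone). Naive and central memory genes fell for 6 of 12 members and rose for 1 (8 and 1 adjusted over the list alone), among them the transcription factor Lef1 (−1.16). Camera called these 5 lists at adjusted p = 9.96e-06, 0.000339, 0.00180, 0.00180 and 0.0148, each with adjusted p = 0.490 with an estimated correlation. It called cell cycle genes (2 of 24 up, 2 adjusted over the list alone) and oxidative phosphorylation (10 up and 1 down of 30, 10 and 1 adjusted over the list alone) at 0.0229 and 0.0481, both with adjusted p = 0.815 with an estimated correlation. Immediate-early genes (4 up and 7 down of 20), interferon-stimulated genes (5 up and 4 down of 27) and MHC class I genes (1 up and 1 down of 14) were not called (adjusted p = 0.281, 0.632 and 0.665).

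In edgeR's test 3037 of 11145 genes changed in T cells (1723 up, 1314 down; 1524 and 1331 after the GC and length correction). Set against B cells, 416 of 7426 differed, 240 of them among the 1882 changed genes compared, with Egr1 at −4.39 (adjusted p = 2.89e-16). Hypoxia and glycolysis (camera adjusted p = 0.309), oxidative phosphorylation (0.196), cell cycle (0.334) and naive genes (0.398) were not called in that comparison. Cluster 3 held the most T cells in the control and macro-metastatic groups and cluster 6 in the pre-metastatic group. The CD8 cluster 20 held 132 and 309 of the 452 and 1117 macro-metastatic T cells against 308 and 61 of 2994 and 1841 in control. Cluster 19, led by Ctla4 and Foxp3 of regulatory T cells, held 94 and 200 of these macro-metastatic cells against 238 and 148 in control. Changes of lists can therefore reflect the mix of subsets, as can those of Pdcd1 and Klrh1, leading genes of cluster 20. The count was 1872 without macro-metastatic replicate 1 and 1429 without macro-metastatic replicate 2. Without control replicate 2 naive genes (0.0543), oxidative phosphorylation (0.725) and cell cycle genes (0.324) lost their calls. So did cell cycle genes without macro-metastatic replicate 1 (0.150) and oxidative phosphorylation without pre-metastatic replicate 1 (0.0725), pre-metastatic replicate 2 (0.0681) and macro-metastatic replicate 2 (0.128) and with the replicate number as a block (0.0553).

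NK cells of macro-metastatic livers held transcripts of granzymes, the proteases of cytotoxic granules, that had no UMI in control NK cells. Gzmd was at least 378-fold higher, Gzmf 262-fold, Gzmc 236-fold (chromosome 14, 56231441 to 56234656) and Gzme 64.8-fold, against a floor of 3 counts over the control group. Gzmf differed most between the libraries, with 2269 unscaled CPM in macro-metastatic replicate 1 and 259 unscaled CPM in macro-metastatic replicate 2. The bounds for Gzmf and Gzmd from macro-metastatic replicate 2 alone are 72.6-fold and 246-fold, and from macro-metastatic replicate 1 alone 637-fold and 639-fold. Gzmd, Gzme and Gzmf share 37.7%, 45.5% and 21.1% of their 31-mers with other genes, so the share of each is uncertain. Cx3cr1, the fractalkine receptor, fell by 2.13 on the log2 scale (SE 0.49, adjusted p = 0.00543), Denn2b by 2.14 (SE 0.41), Cpeb1 by 2.53 (SE 0.55) and Zfp217 by 2.01 (SE 0.56). Hypoxia and glycolysis genes rose for 10 of 17 members and fell for 1 (12 and 1 adjusted over the list alone), among them the vascular growth factor Vegfa (3.49, SE 0.32). Immediate-early and heat-shock genes rose for 7 of 20 and fell for 1 (10 and 2 adjusted over the list alone; Nr4a1 1.75). Of 17 cytotoxic effector genes 2 rose and 3 fell (2 and 3 adjusted over the list alone), the falling ones including Zeb2 (−1.29). Camera called hypoxia and glycolysis and immediate-early genes (adjusted p = 3.64e-07 and 0.00745), both with adjusted p = 0.209 with an estimated correlation. Cytotoxic effector genes, inhibitory receptor genes (3 up and 2 down of 6), oxidative phosphorylation (6 of 29 up), MHC class I genes (2 of 14 up), cell cycle genes (1 of 9 up) and interferon-stimulated genes (0 of 10) were not called (adjusted p = 0.821, 0.272, 0.176, 0.312, 0.312 and 0.846). In edgeR's test 744 of 5947 genes changed (562 up, 182 down; 450 and 240 after the GC and length correction). Relative to B cells 103 of 5250 differed, 62 of them among the 530 changed genes compared, with Denn2b at −3.13 (adjusted p = 0.00563). Immediate-early genes stayed called there (camera adjusted p = 0.00294, 0.508 with an estimated correlation), hypoxia and glycolysis genes did not (0.509). All cells named NK lay in cluster 17, with 50 and 143 cells in the macro-metastatic libraries. Cluster 13, left unnamed because its leading genes held more NK markers than markers of T cells, its best match, held 257 and 345 cells of the control libraries, 424 and 274 of the pre-metastatic and 64 and 148 of the macro-metastatic libraries. The count was 493 without control replicate 1 and 495 without control replicate 2, where Zfp217 lost its call (0.0943). Without macro-metastatic replicate 2 Cx3cr1 (0.115), Zfp217 (0.327) and the immediate-early list (0.0653) lost theirs. In DESeq2's Wald test Gzmd (adjusted p = 0.132), Gzmf (0.149), Zfp217 (0.131) and Cx3cr1 (0.0766) were not called, nor was Zfp217 after thinning (0.0715).

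**Figure D3:**
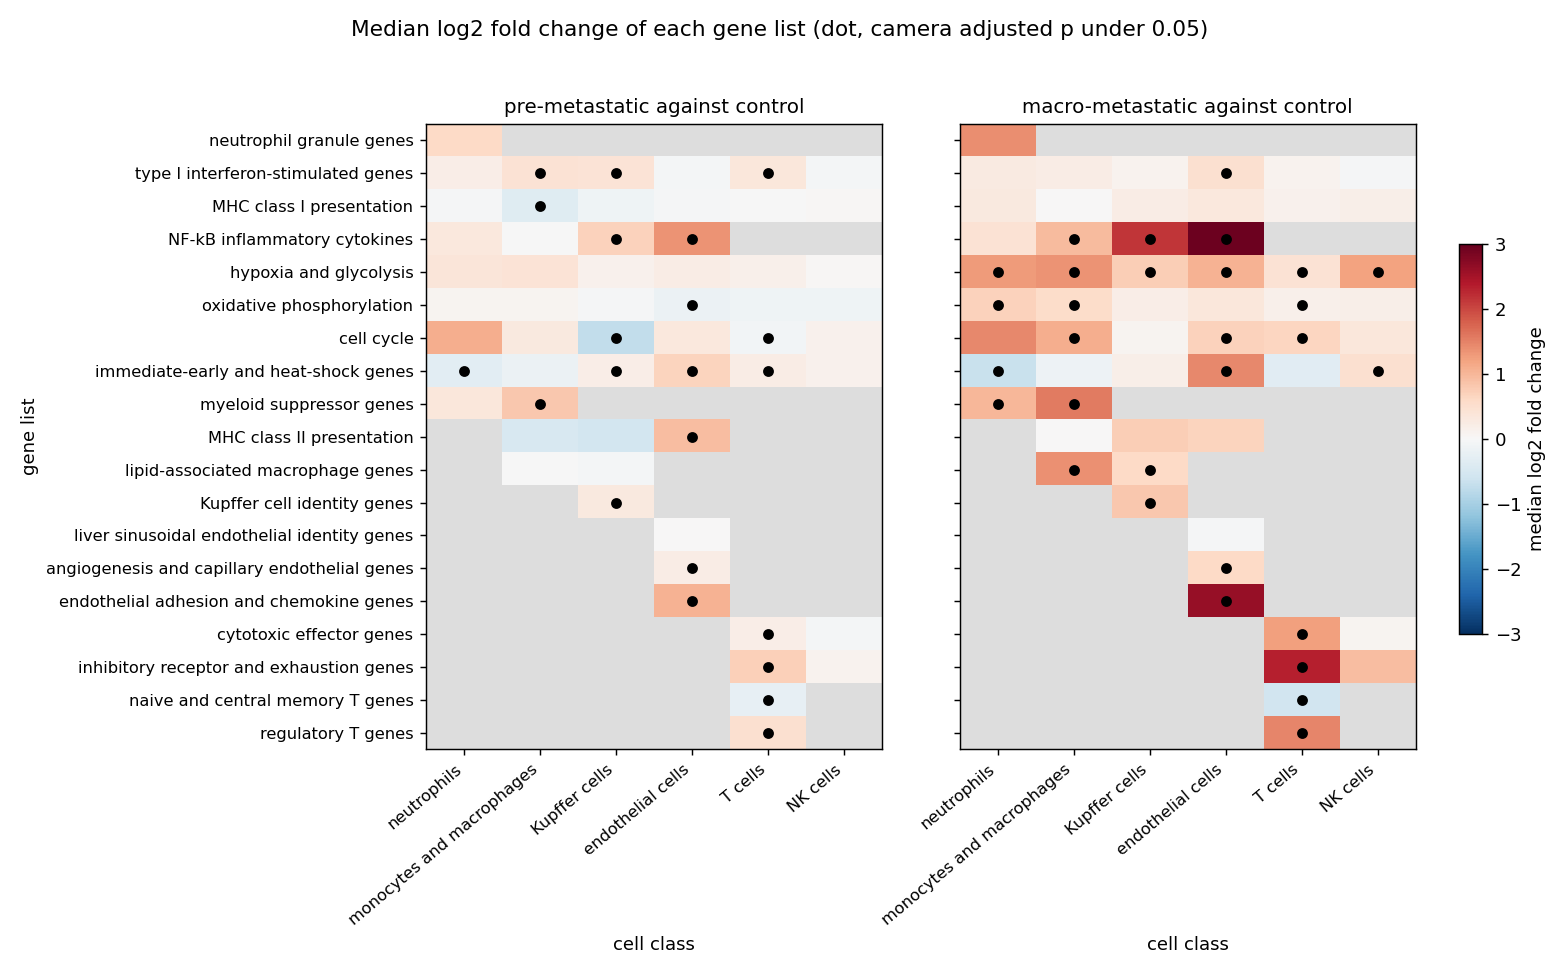
Median log2 fold change (colour scale) of each fixed gene list (vertical axis) in each cell class (horizontal axis), for pre-metastatic and macro-metastatic against control livers, with a dot where camera at the preset correlation gave an adjusted p under 0.05 and grey where a list was not tested. Inhibitory receptor genes in T cells and NF-kB inflammatory cytokines in Kupffer and endothelial cells carry a dot in both comparisons.

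**Figure D4:**
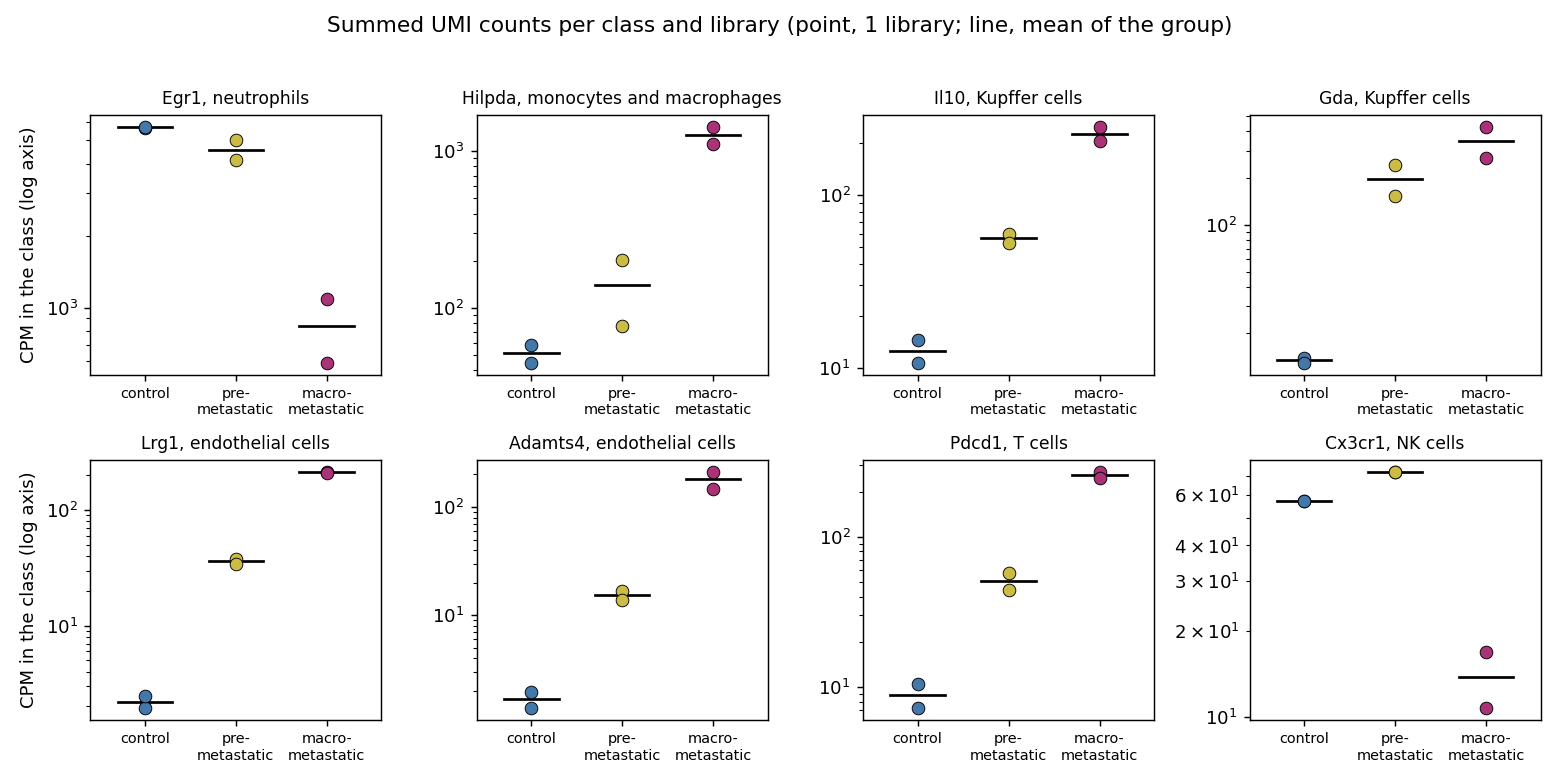
Level of 8 named genes (CPM in the summed cells of a class, log axis) in the 3 groups, with points for libraries and lines for group means. Pdcd1 in T cells had means of 8.87, 51.0 and 258 CPM and Lrg1 in endothelial cells of 2.19, 36.0 and 212 CPM in control, pre-metastatic and macro-metastatic livers. Whether RNA from other cells adds to the pre-metastatic level of Lrg1 was not tested.

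Before macro-metastases, fewer genes passed the test. In pre-metastatic against control livers Gda rose by 3.88 on the log2 scale in Kupffer cells (SE 0.31, 199 ± 63.6 against 13.4 ± 0.728 CPM, adjusted p = 0.00400), with Il10 (2.15, SE 0.19), Cxcl13, a chemokine for B cells (2.01, SE 0.30), and the cytokine receptor subunit Csf2rb (1.98, SE 0.24). Crip1 (−1.75), Atox1, a copper chaperone (−1.15), and Arhgap23 (−0.79) fell. In endothelial cells Lrg1 rose by 4.01 (SE 0.19, 36.0 ± 2.45 against 2.19 ± 0.354 CPM, adjusted p = 0.000553), with Serpina3n (3.19, SE 0.33), Adamts4 (3.15, SE 0.28) and the hepatocyte growth factor Hgf (2.67, SE 0.27). Acute-phase transcripts, which hepatocytes make, rose in the same endothelial sums. The rule on levels in other classes pooled all libraries. It cannot tell whether RNA from other cells gave the pre-metastatic levels of Lrg1 and Serpina3n. In T cells Pdcd1 rose by 2.55 (SE 0.23, 51.0 ± 9.43 against 8.87 ± 2.26 CPM, adjusted p = 0.00106). Klrh1 rose from 0.311 ± 0.05 to 20 ± 7.38 CPM, with 2 and 1 UMIs in the control libraries and 56 and 80 in the pre-metastatic libraries. The glucocorticoid-responsive genes Klf9 (1.10, SE 0.18) and Fkbp5 (0.99, SE 0.17) rose and Cd52 fell by 1.17 (SE 0.20). By edgeR's quasi-likelihood test 60 genes changed in Kupffer cells (38 up, 22 down), 17 in endothelial cells (17 up), 36 in T cells (32 up, 4 down), 4 in NK cells (2 up, 2 down), 0 in neutrophils and 0 in monocytes and macrophages. For the last 2 classes 608 and 686 genes had an unadjusted p under 0.05 and DESeq2 called 24 and 19, while the replicate number as a block gave 10 and 0. Set against B cells, 6 genes differed in Kupffer cells and 13 in T cells. Without control replicate 1 or control replicate 2 the counts were 0 and 0 in Kupffer cells, with all 7 genes named at adjusted p of 0.18 to 0.449 and of 0.259 to 0.361 (Cxcl13, Crip1, Atox1 and Arhgap23 at 0.104 to 0.326 without pre-metastatic replicate 1). They were 1 and 1 in endothelial cells, where Lrg1 kept its call and the other 3 genes had 0.142 to 0.292 and 0.310 to 0.417. In T cells the count was 3 without control replicate 1, where Klrh1, Klf9, Fkbp5 and Cd52 had adjusted p of 0.0726 to 0.35. Fkbp5 (0.127) and Cd52 (0.126) also lost their calls without control replicate 2, and Klf9, Fkbp5 and Cd52 without pre-metastatic replicate 1 (0.0753 to 0.0976). Klf9 and Cd52 lost theirs without macro-metastatic replicate 1 (0.0605 and 0.0740) or macro-metastatic replicate 2 (0.0668 and 0.0862). Without pre-metastatic replicate 2 the calls of Cxcl13 (0.0505) and Arhgap23 (0.1) in Kupffer cells and of Serpina3n (0.0829) and Adamts4 (0.0588) in endothelial cells were lost. Other settings ended calls as well. With the replicate number as a block these were Cxcl13 (0.0584), Arhgap23 (0.07), Klf9 and Fkbp5 (both 0.0522). Among genes screened for RNA from other cells they were Arhgap23 (0.0532), Klf9 (0.129), Fkbp5 (0.143) and Cd52 (0.164). Stricter cell filters ended those of Cxcl13 (0.0545), Atox1 (0.0715), Arhgap23 (0.0922), Fkbp5 (0.0649) and Cd52 (0.065). Thinning ended those of Klrh1 (0.0577), Klf9 (0.104), Fkbp5 (0.108) and Cd52 (0.0701), the GC and length correction that of Fkbp5 (0.0524), and DESeq2's size factors those of Fkbp5 (0.0506) and Cd52 (0.0525). Leaving out cluster 10 ended those of Cxcl13 (0.0613) and Arhgap23 (0.0588). The number of changed genes was 23 in Kupffer cells, 28 in endothelial cells and 76 in T cells without pre-metastatic replicate 1. Without pre-metastatic replicate 2 it was 34 in Kupffer cells, 8 in endothelial cells, 58 in T cells and 16 in neutrophils, with 105 in monocytes and macrophages. Leaving out macro-metastatic replicate 1 or macro-metastatic replicate 2 gave 276 and 266 in Kupffer cells, 47 and 46 in endothelial cells, 27 and 22 in NK cells and 4 and 4 in neutrophils.

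In pre-metastatic against control livers camera called 44 of 95 lists tested at the preset correlation and 0 with an estimated correlation, and few members passed singly. Only part of these 44 is described here. In Kupffer cells NF-kB inflammatory cytokines rose for 1 of 20 members (10 adjusted over the list alone), the feedback regulator Tnfaip3 (1.15, SE 0.17). Cell cycle genes fell for 1 of 24 (15 adjusted over the list alone), Ube2c (−1.24, SE 0.17). Kupffer cell identity genes rose for 1 of 18 (6 adjusted over the list alone), Marco (1.64, SE 0.17). Endothelial adhesion genes rose for 1 of 15 members (7 adjusted over the list alone), Lrg1. NF-kB inflammatory cytokines were called with 0 of 19 members up in endothelial cells (10 adjusted over the list alone). Inhibitory receptor genes rose for 1 of 13 members in T cells (5 adjusted over the list alone), Pdcd1. Camera called these 6 at adjusted p = 5.49e-07, 1.72e-10, 0.00560, 1.56e-06, 4.41e-10 and 6.42e-05. Their adjusted p with an estimated correlation was 0.574, 0.390, 0.452, 0.219, 0.337 and 0.334. Naive T genes were called downward with 0 of 12 members passing (2 adjusted over the list alone; camera adjusted p = 0.00125, 0.334 with an estimated correlation). Myeloid suppressor genes in monocytes and macrophages were called upward with 0 of 18 members passing (3 adjusted over the list alone; 0.00228, 0.413 with an estimated correlation), and were not called relative to B cells (0.603). Immediate-early and heat-shock genes were called upward in endothelial, Kupffer and T cells and downward in neutrophils, each with 0 of 20 members passing (3, 0, 0 and 3 adjusted over the list alone). Their camera adjusted p was 2.21e-06, 0.0416, 0.0353 and 0.0415, and 0.521, 0.837, 0.334 and 0.446 with an estimated correlation. Relative to B cells they were called in endothelial cells (2.48e-06, 0.565 with an estimated correlation) and neutrophils (0.0411, 0.881 with an estimated correlation) but not in Kupffer (0.203) or T cells (0.198). In endothelial cells this call was lost without pre-metastatic replicate 2 (0.0684). It was lost in Kupffer cells without control replicate 1 (0.244), pre-metastatic replicate 2 (0.625), macro-metastatic replicate 1 (0.0772) or macro-metastatic replicate 2 (0.0760). It was lost in T cells without control replicate 1 (0.0806), control replicate 2 (0.108), pre-metastatic replicate 2 (0.17), macro-metastatic replicate 1 (0.0685) or macro-metastatic replicate 2 (0.0623), and in neutrophils without control replicate 1 (0.272), control replicate 2 (0.246) or pre-metastatic replicate 1 (0.136). Acute-phase transcripts rose for 7 of 11 members in Kupffer cells, 6 of 12 in endothelial cells, 3 of 11 in T cells and 2 of 5 in NK cells (10, 12, 8 and 3 adjusted over the list alone), with camera adjusted p = 1.19e-15, 5.84e-25, 1.96e-15 and 2.57e-08 and adjusted p = 0.0702, 0.0776, 0.334 and 0.196 with an estimated correlation. Neutrophil transcripts rose for 2 of 12, 5 of 12 and 4 of 10 members in Kupffer, endothelial and T cells (7, 9 and 8 adjusted over the list alone), with camera adjusted p = 2.36e-08, 1.53e-17 and 1.50e-13 and adjusted p = 0.360, 0.0776 and 0.334 with an estimated correlation. Tnfaip3, Ube2c and Marco lost their calls without control replicate 1 (0.265 to 0.427) or control replicate 2 (0.270 to 0.351). Tnfaip3 and Ube2c lost theirs without pre-metastatic replicate 1 (0.0808 and 0.173) or pre-metastatic replicate 2 (0.0973 and 0.0580). Kupffer identity genes lost their call without control replicate 2 (0.0531), inhibitory receptor genes without pre-metastatic replicate 2 (0.0538). Naive genes lost theirs without control replicate 2 (0.0801) or pre-metastatic replicate 2 (0.0611).

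Between macro-metastatic and pre-metastatic livers, Il10 rose by 4.64 on the log2 scale in monocytes and macrophages (SE 0.33, 219 ± 7.68 against 9.22 ± 2.76 CPM, adjusted p = 0.00251), with Ecm1 (4.52, SE 0.66) and the chemokine Ccl7 (4.45, SE 0.81, with B cells at 4.13). In neutrophils Hilpda (3.68, SE 0.35, with B cells at 2.24) and Cd177 (4.24, SE 0.57) rose and Egr1 (−2.45, SE 0.29), Trp53inp1 (−2.42, SE 0.23) and Tsc22d3, a glucocorticoid-induced gene (−2.24, SE 0.22), fell. In Kupffer cells Crip1 (4.62, SE 0.23) and H2-DMa, which helps load MHC class II (4.13, SE 0.23), rose, with B cells at 3.52 and 3.22, and Clec14a (−5.26) and Tmem204 (−4.89) fell. In endothelial cells Sele rose by 4.01 (SE 0.61) and Mt2 by 5.23 (SE 0.61, with B cells at 3.71) and Ccn2 fell by 2.78 (SE 0.33). In T cells Gzmf rose by 4.97 (SE 0.43) and Egr1 fell by 2.71 (SE 0.20) and Cd40lg, a ligand of T cell help, by 2.63 (SE 0.40). Cluster 6, with Cd40lg among its leading genes, held 890 and 606 of the 1879 and 1518 pre-metastatic T cells. It held 52 and 122 of the 452 and 1117 macro-metastatic ones, so the fall of Cd40lg can reflect the mix of subsets. In NK cells Gzmc rose from 2.50 ± 3.54 CPM, with 0 and 2 UMIs in the pre-metastatic libraries, to 1083 ± 509 CPM. Cx3cr1 fell by 2.47 (SE 0.48) in these cells. NF-kB inflammatory cytokines rose for 17 of 20 members in Kupffer cells and 10 of 19 in endothelial cells (18 and 11 adjusted over the list alone), cell cycle genes for 18 of 24 in Kupffer cells (19), lipid-associated macrophage genes for 6 of 18 in monocytes and macrophages (8), adhesion genes for 9 of 15 in endothelial cells (11) and inhibitory receptor genes for 9 of 13 in T cells (9). Camera called 49 of 95 lists in this comparison, and only part of them is described here. The 6 just named had camera adjusted p = 9.25e-07, 7.26e-06, 5.58e-06, 2.58e-06, 4.99e-05 and 9.77e-05. The lists had, with an estimated correlation, adjusted p = 0.548, 0.571, 0.548, 0.246, 0.391 and 0.533. Hypoxia and glycolysis genes rose for 7 of 20, 7 of 24, 15 of 24, 11 of 24, 11 of 23 and 11 of 17 members in neutrophils, monocytes and macrophages, Kupffer, endothelial, T and NK cells (9, 9, 15, 14, 11 and 12 adjusted over the list alone), with camera adjusted p = 0.000171, 2.58e-06, 0.00123, 7.26e-06, 0.00630 and 1.32e-07 and adjusted p = 0.386, 0.391, 0.548, 0.391, 0.533 and 0.288 with an estimated correlation. Tested relative to B cells, this list was called in monocytes and macrophages, Kupffer and endothelial cells (camera adjusted p = 0.00673, 0.0115 and 0.00133, and 0.363, 0.290 and 0.259 with an estimated correlation). It was not called in neutrophils (0.460), T cells (0.280) and NK cells (0.0700). On the members that could be compared with B cells, camera called lipid-associated macrophage genes in monocytes and macrophages (0.0456, 0.363 with an estimated correlation). It did not call cell cycle genes in Kupffer cells (0.977), a list not tested without cluster 10. Cluster 10 held 491 and 714 of the 1255 and 1294 pre-metastatic Kupffer cells and 12 and 13 of the macro-metastatic ones. Without it cluster 31, led by cell cycle genes among others, made up 41 of 764 and 58 of 580 pre-metastatic cells. It made up 86 of 1783 and 136 of 2056 macro-metastatic cells, so the rise can reflect the mix of clusters.

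By edgeR's quasi-likelihood test 838 genes changed in neutrophils (444 up, 394 down), 800 in monocytes and macrophages (649 up, 151 down), 4590 in Kupffer cells (2451 up, 2139 down), 1464 in endothelial cells (1179 up, 285 down), 2409 in T cells (1343 up, 1066 down) and 623 in NK cells (480 up, 143 down). Set against B cells, 66, 63, 561, 79, 233 and 55 differed. After the GC and length correction 321, 245, 2118, 672, 1116 and 361 genes were up and 296, 108, 2074, 363, 894 and 169 down. Without cluster 10 the Kupffer cells had 1801 up and 762 down. With the replicate number as a block 1569 genes changed in neutrophils. Without pre-metastatic replicate 1 the counts were 311, 308, 2766, 310, 1047 and 261 in the same order. Without pre-metastatic replicate 2 they were 480, 1306, 2802, 454, 1937 and 374. Without macro-metastatic replicate 1 they were 477 in neutrophils, 46 in monocytes and macrophages, 2506 in endothelial cells and 1083 in T cells. Without macro-metastatic replicate 2 they were 192 in monocytes and macrophages and 874 in T cells. Without control replicate 1 or 2 they were 811 and 819 in endothelial cells. Without macro-metastatic replicate 2 T cell hypoxia and glycolysis genes lost their call (0.0597). Ecm1 lost its call without pre-metastatic replicate 1 (0.0536) or macro-metastatic replicate 1 (0.0594), and Ccl7 without macro-metastatic replicate 1 (0.0729) or macro-metastatic replicate 2 (0.0719).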

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

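The comparison of each class with the B cells of the same libraries, the thinning to a common depth and the values on a batch or a common response were chosen only after the results were seen. The tests of GC content and length, of RNA from other cells, of near-identical genes and of endothelial transcripts in Kupffer cells were set before their results were seen.

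The change between groups differed from that in B cells, by a test of the difference itself, for many genes in macro-metastatic against control livers: 153 in neutrophils, 48 in monocytes and macrophages, 931 in Kupffer cells, 316 in endothelial cells, 416 in T cells and 103 in NK cells. In macro-metastatic against pre-metastatic livers it differed for 66, 63, 561, 79, 233 and 55 genes in the same order, and in pre-metastatic against control livers for 6 genes in Kupffer cells and 13 in T cells.

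The first pattern is the set of 139 genes higher in every class of the macro-metastatic libraries. Removing each library's trend on GC content and transcript length left a median log2 fold change of 1.70 (1.473 to 1.877 over classes, from 2.22). That trend therefore does not account for the whole. Thinning the summed counts to the shallowest library left 2.23. Thinning leaves the expected ratios between libraries unchanged, so it cannot test an effect of depth that arose before the counts were summed. Free RNA at the level seen from neutrophils could supply 5.60% of the rise of the median gene in B cells. That level came from S100a8 and S100a9. For genes present in many classes free RNA could supply more, which this test cannot exclude. Of the 139 genes, 18.7% share over 10% of their 31-mers with another gene, against 8.70% of other genes. A difference in the making of the macro-metastatic libraries and a response common to all cells of these livers cannot be told apart, since every macro-metastatic library belongs to that group and the same genes changed by a median of 0.118 in the pre-metastatic libraries. Both remain open.

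The next pattern is the rise of neutrophil transcripts in lymphocytes and endothelial cells. Within a library these genes kept nearly the ratios to S100a8 that they have in its neutrophils, with a median absolute difference of log2 ratios of 0.435 over 64 comparisons, 37 of them under 0.5 and 9 at 1 or more. The median was 0.396 in the macro-metastatic and 0.496 in the pre-metastatic libraries. This is consistent with RNA from neutrophils, whose share of cells rose in the same livers. Of the 9 comparisons 8 were in pre-metastatic libraries. Il1r2 made up 6 of these, 1.32 to 2.09 above its ratio in neutrophils, so for Il1r2 in pre-metastatic livers expression by the other cells stays open.

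The last pattern is the high level of endothelial transcripts in Kupffer cells of the control libraries. T cells of these libraries held them at a median of 10.7% of the Kupffer level, which argues against free endothelial RNA. The log2 percent of the endothelial level had an SD of 0.616 over 11 markers, as endothelial cells or fragments joined to Kupffer cells could give. Lower levels in macro-metastatic livers, where the median was 2.37%, may then follow from fewer joined cells. Cdh5 and Pecam1 stayed at 43.0% and 25.8% there, so their source is open, and a change within Kupffer cells was not tested.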

How the results depend on the processing

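The B cell comparison, the GC and length correction, thinning and leaving out the endothelial-rich Kupffer cluster were chosen only after the results were seen; the other settings were planned. For every changed value below the cause was not tested, except that fewer libraries or fewer tested genes can by themselves lower a count. With 2 libraries per group and neutrophil and monocyte sums of few cells in control, 2-fold changes were mostly out of reach in these classes. Of the 112 named genes, 32 could be tested relative to B cells and 9 were called. With an estimated correlation 0 of 139 called lists stayed called. The sign of median, mean and test differed for 0 called lists.

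For cell classes, macro-metastatic against control livers gave 7 calls; pre-metastatic against control livers gave 2, and 4 with DESeq2; macro-metastatic against pre-metastatic livers gave 0, and 2 with TMM scaling, 1 with immune cells only, 1 at resolution 2 and 5 with DESeq2. Leaving out a library gave 2 to 10, 0 to 3 and 0 to 8 calls in these comparisons.

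In macro-metastatic against control livers the calls relative to B cells were 153 in neutrophils, 48 in monocytes and macrophages, 931 in Kupffer cells, 316 in endothelial cells, 416 in T cells and 103 in NK cells. Without a low count filter there were 1229 in neutrophils and 1453 in monocytes and macrophages, DESeq2 gave 1002 in monocytes and macrophages and 369 in NK cells, thinning 531 in neutrophils, the GC and length correction 215 in monocytes and macrophages, and Kupffer cells less the endothelial-rich cluster 3030. Leaving out a library gave 119 to 922 in neutrophils, 0 to 804 in monocytes and macrophages, 2717 to 4776 in Kupffer cells, 580 to 3741 in endothelial cells, 1429 to 3171 in T cells and 493 to 713 in NK cells.

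In pre-metastatic against control livers, the settings without a low count filter gave 79 calls in neutrophils, 178 in monocytes and macrophages, 877 in Kupffer cells, 537 in endothelial cells, 325 in T cells and 26 in NK cells. DESeq2 gave 24, 19, 266, 153 and 99 in the first 5. Genes screened for RNA from other cells gave 28 in Kupffer cells, 4 in endothelial cells, 2 in T cells and 0 in NK cells, and stricter cell filters gave 29, 7 and 23 in Kupffer, endothelial and T cells. Thinning gave 6 in neutrophils, 91 in Kupffer cells, 11 in endothelial cells and 3 in T cells, and the GC and length correction 22 in T cells and 12 in NK cells. Relative to B cells there were 6 in Kupffer cells, 0 in endothelial cells, 13 in T cells and 0 in NK cells, and Kupffer cells less the endothelial-rich cluster had 36. Leaving out a library gave 0 to 16 in neutrophils, 0 to 105 in monocytes and macrophages, 0 to 276 in Kupffer cells, 1 to 47 in endothelial cells, 3 to 76 in T cells and 4 to 27 in NK cells.

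In macro-metastatic against pre-metastatic livers, the settings relative to B cells gave 66 in neutrophils, 63 in monocytes and macrophages, 561 in Kupffer cells, 79 in endothelial cells, 233 in T cells and 55 in NK cells. Without a low count filter there were 1857 in monocytes and macrophages and 2756 in endothelial cells, DESeq2 gave 1481 in monocytes and macrophages and 316 in NK cells, thinning 293 in neutrophils and 191 in monocytes and macrophages, the GC and length correction 353 in monocytes and macrophages, and Kupffer cells less the endothelial-rich cluster 2563. Leaving out a library gave 311 to 733 in neutrophils, 46 to 1306 in monocytes and macrophages, 2766 to 4304 in Kupffer cells, 310 to 2506 in endothelial cells, 874 to 2557 in T cells and 261 to 660 in NK cells.

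Leaving out a library left 128 to 142 lists and 83 to 106 named genes called. A change of direction was seen for cell cycle in T cells, pre-metastatic against control, without pre-metastatic replicate 1 (camera adjusted p = 0.000681; from 8.00e-14 without pre-metastatic replicate 2 to 0.894 without control replicate 1), for cytotoxic effector genes in T cells in the same comparison without pre-metastatic replicate 2 (0.468; from 0.000147 without pre-metastatic replicate 1 to 0.73 without control replicate 2), and for Mki67 (−0.52) and Top2a (−1.04) in Kupffer cells, macro-metastatic against control, less the endothelial-rich cluster.

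Whether the replicate numbers pair the samples stays open. Deviations from the group means of samples with the same number correlated by −0.194 to 0.420, and by 0.121 to 0.420 in neutrophils. In 9 of 19 classes, unnamed and mixed cells included, replicate 1 lay on the same side of replicate 2 in every group, against 4.75 expected by chance. With the replicate block there were 11 calls among classes in macro-metastatic against control livers and 5 in macro-metastatic against pre-metastatic livers, and in neutrophils 10 genes in pre-metastatic against control livers and 1569 in macro-metastatic against pre-metastatic livers.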

Other observations

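The B cell comparison was added after the data were seen, and the genes of this part were chosen after their values were seen.

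Saa1, a serum amyloid transcript made by hepatocytes in the acute-phase response, was also read in B, T, Kupffer and endothelial cells. Its fold changes in these classes were larger before macro-metastases than with them. Saa1 had log2 fold changes against control of 7.97 (SE 0.58) in B cells, 7.84 in T cells, 7.79 in Kupffer cells and 6.85 in endothelial cells of pre-metastatic livers, and of 5.40, 5.31, 6.51 and 5.03 in the same classes of macro-metastatic livers. Saa1 shares 39.1% of its 31-mers with other genes, so its level is uncertain. Between macro-metastatic and pre-metastatic livers acute-phase transcripts fell for 6 of 11 members in T cells, 6 of 8 in B cells, 5 of 11 in neutrophils, 3 of 10 in monocytes and macrophages and 3 of 5 in NK cells (6, 6, 5, 6 and 4 adjusted over the list alone) and rose for 2, 1, 2, 1 and 0, with camera adjusted p = 0.0217, 0.0108, 0.0232, 0.00665 and 0.0266. With an estimated correlation the lists had adjusted p = 0.533, 0.393, 0.481, 0.581 and 0.498. They were not called in Kupffer cells (2 up and 3 down of 11, 0.768) or endothelial cells (3 up and 5 down of 12, 0.235). Without pre-metastatic replicate 1 the call was lost in T cells (0.0781), neutrophils (0.0648) and NK cells (0.161), and without macro-metastatic replicate 1 in monocytes and macrophages (0.0624).

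B cells, the class set beside all others, changed in 1581 genes in macro-metastatic against control livers, 25 in pre-metastatic against control livers and 1206 in macro-metastatic against pre-metastatic livers, by edgeR's quasi-likelihood test. Nr4a3, an immediate-early nuclear receptor, rose by 3.01 on the log2 scale (SE 0.33, 326 ± 144 against 38.1 ± 22.9 CPM) and H2-DMa, which helps load MHC class II, by 3.35 (SE 0.22), while Zfp36l2, an RNA-binding protein that promotes mRNA decay, fell by 2.37 (SE 0.23). Cd52, a surface glycoprotein of lymphocytes, fell by 1.46 (SE 0.19) in pre-metastatic B cells.

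Hepatocytes of control livers lay in clusters 22 and 32 and those of pre-metastatic livers in clusters 18 and 26, the latter led by Saa1. Predicted doublets included, of the 874 cells of cluster 22, 396 and 474 were from the control libraries. Cluster 11, unnamed for its low UMI counts, held 671 and 815 cells of the macro-metastatic libraries against 111 and 100 of the control libraries.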
